A study of Rattus norvegicus with 36 samples.

How the data were processed

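Total RNA of 2 rat muscle samples, extraocular muscle (EOM) and a leg sample of gastrocnemius and soleus, was hybridised to Affymetrix RG-U34A arrays by the authors, per the labels. The 36 arrays form 12 groups, 1 for each muscle at each of 6 postnatal ages, with 3 arrays per group. The group, the age and the replicate number were taken from the labels. The labels do not say that replicates were separate animals.

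The deposited table holds 1 intensity per probe set and array on a linear scale, with 44 zeros. All arrays have the same trimmed mean of 1499.8 between the 2nd and 98th percentiles, so the deposited intensity values had been scaled to a common target. The software that summarised the probes is not given in the sources used here. Array maxima ranged from 20938.3 to 49844.7, and 9.954% to 23.44% of the values of an array lay at or under the floor described next.

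The deposited scaling was kept. Values were floored at the 20th percentile of all values (intensity 100.9, log2 6.66) and turned to log2. The 59 Affymetrix control probe sets were left out, and a probe set was tested if it exceeded the 40th percentile (intensity 320.4) on 3 or more of the 36 arrays, whatever the group. Of the 8799 probe sets, 6672 were tested. The platform annotation, dated 2016, gave 1 gene symbol to 7006 probe sets, several to 308, and none to 1426 that are unnamed here. By gene identifier 6994 of the probe sets with 1 symbol matched the gene table used, and 0 symbols had to be updated. Tested probe sets with 1 symbol numbered 5451, for 3889 genes. A difference against a group whose 3 arrays all lay at the floor is a lower bound and is written as "at least", as are folds where 1 or 2 of the 3 arrays lay there. Log2 differences that involve an array at the floor or near the top of the scale can be smaller than the real ones, and no fold is given where an array of the brighter group lay in the brightest range of the scale or where the dimmer group lay above the floor but under the filter level on all 3 arrays, a rule set after seeing the data.

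Group means were fitted over all 36 arrays with limma 3.58.1 in R 4.3.3, with a trended prior on the variance, 24 residual degrees of freedom and 5.84 prior ones. Moderated tests compared EOM with leg at each age, day 45 with day 0 in each muscle, and the difference between these changes. A moderated F test took all ages of a muscle. Benjamini-Hochberg adjustment was made within each comparison, with a threshold of 0.05. Folds at or above 2 are counted beside the calls. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

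The test, the floor, the filter, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. By that rule, each gene with 1 symbol is represented by its probe set of highest mean. For the 5 main comparisons (EOM against leg at days 0 and 45, day 45 against day 0 in each muscle, and the difference of the changes) the 8 largest differences each way past the threshold are named. Between 2 groups, all 3 arrays of one also had to lie above all 3 of the other. For days 7, 14, 21 and 28 the 3 largest each way are named. Up to 4 members past the threshold are named from each list described, or up to 2 as values where none passed. Myh1, Myh2, Myh3, Myh4, Myh7, Myh8, Myh13, Chrng and Chrne are followed in every comparison.

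The 26 lists covered developmental isoforms, adult fast and slow fibre genes, glycolysis, oxidative phosphorylation, fatty acids, cell cycle, extracellular matrix, calcium handling, neuromuscular junction, myogenic regulators, insulin-like growth factors, dystrophin complex, regional patterning, antioxidant defence, ribosomal proteins, proteasome and immediate early genes. They also covered markers of Schwann cells and axons, endothelium and smooth muscle, adipocytes, leukocytes, erythroid cells, lacrimal and Harderian glands, eye, and cartilage and bone. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation as the alternative. Of the 476 genes on any list, 21 were on more than 1.

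Replicate numbers were checked for pairing through the correlation of deviations from the group means. At day 7 the EOM and leg arrays numbered 1, 2 and 3 correlated at 0.17, 0.13 and 0.3, at day 14 at 0.12, 0.11 and 0.16, and at day 21 at 0.1, 0.15 and 0.37, each over 0.1 before rounding. At these ages the numbers may pair the samples, from the data and not from the labels. But same-numbered arrays of all groups also correlated, with medians of 0.082, 0.0707 and 0.15 for numbers 1, 2 and 3. Arrays of different number and group had a median of -0.0553. Pairing is therefore not told apart from a deviation shared by number. The main fits used no replicate block.

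The fits were tested on simulated data with 200 of 6672 probe sets changed. For EOM against leg at day 45, 53% of 2-fold and 94% of 4-fold changes were recovered with 10 unchanged probe sets called. For EOM at day 45 against day 0 the shares were 53% and 95% with 7, for the F test in EOM 54% and 95% with 13, and for the difference of the changes 29% and 81% with 5. Comparisons simulated without change gave 0 calls. In a simulation of EOM against leg at day 45 over 3889 genes, 1 list shifted by 0.5 log2 units was called and 0 of the others. The simulated noise was independent between probe sets and between arrays. The changed probe sets lay away from the floor and the top of the scale. These runs therefore cannot show how many false calls arise where genes are correlated or arrays deviate together.

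Alternatives were quantile normalization, scaling to the same median, other floors and filters, 1 probe set per gene, leaving out probe sets whose suffix marks shared probes, fitting only the arrays compared, no trend in the variance, a replicate block, and leaving out each array in turn. The closing section gives their effect.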

Results

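RNA from 2 rat muscles was measured with Affymetrix RG-U34A arrays during the first weeks after birth. The extraocular muscles (EOM), which move the eye, were set against a leg sample of gastrocnemius and soleus, which are limb muscles of mostly fast and mostly slow fibres. Each muscle was sampled at postnatal days 0, 7, 14, 21, 28 and 45 with 3 arrays at each age, which gave 36 arrays in 12 groups. Of 8799 probe sets, 6672 were bright enough to be tested. Array medians ranged from 418.7 to 652.2 intensity units, and arrays of the same group correlated at 0.877 to 0.953 across probe sets. With 3 arrays in a group, the number of arrays limits the precision. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples. Log2 differences are given with the standard error of the fit, and adjusted p-values are those of limma. Each group mean rests on 3 arrays, but the variance behind the error is pooled over all 12 groups. The error therefore does not measure the spread of the groups compared alone. "Fold" values are ratios of the group means on the log2 scale.

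**Figure D1:**
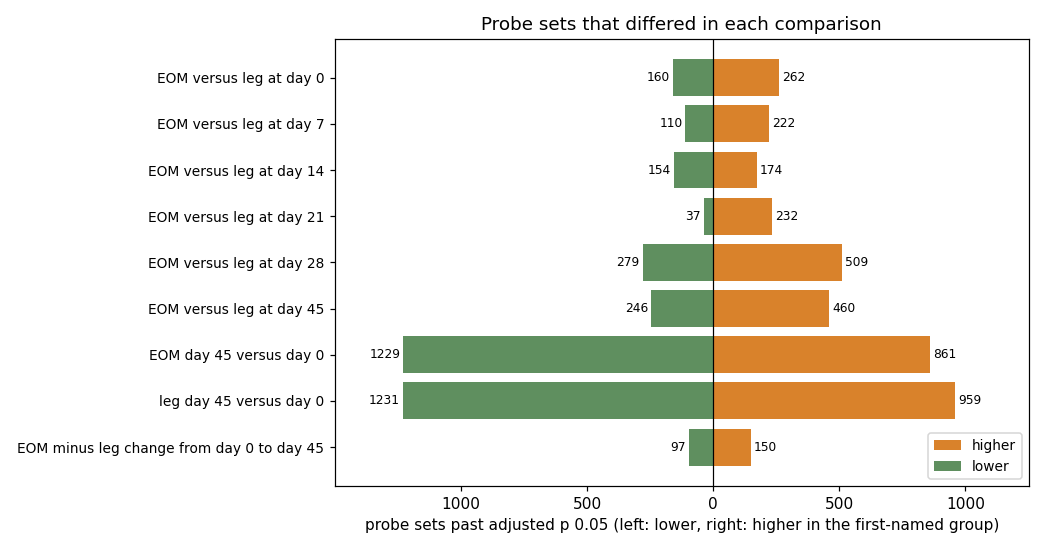
Probe sets past an adjusted p of 0.05 in the 9 comparisons with a direction, with those higher in the first-named group drawn to the right and those lower to the left. The changes from day 0 to day 45 in each muscle (2090 probe sets in EOM and 2190 in leg) were more numerous than the differences between the muscles at any single age, which were 269 to 788.

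The muscles were first compared at birth, at day 0. Krt19, a keratin of simple epithelia (4.72 ± 0.48), Krt5, a keratin of basal epithelial cells (4.28 ± 0.85), and Lgals7, a galectin of stratified epithelia (4.60 ± 0.53), were higher in EOM. Mia, a secreted protein of cartilage and pigment cells, was higher by 4.83 ± 0.34 (adjusted p = 7.6e-11), with leg close to the detection floor. Alx1, a homeobox factor of the developing face, was at the detection floor on all 3 leg arrays and at least 22.1-fold higher in EOM. Cyp1b1, a cytochrome P450 that is expressed in tissues of the eye, was higher by 4.45 ± 0.38. Sox10, a transcription factor of neural crest and Schwann cells, was higher by 4.04 ± 0.42. Genes lower in EOM included Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum (-3.25 ± 0.40), and Pdk4, a kinase that switches off pyruvate dehydrogenase (-3.09 ± 0.61). Thbs4 and Fmod, matrix proteins of tendon and of its junction with muscle, were lower by -2.76 ± 0.27 and -2.45 ± 0.33. The globin genes Hbb (-3.02 ± 0.79) and Hbb-b1 (-2.96 ± 0.73), the epidermal keratin Krt1 (-2.96 ± 0.56) and the ribosomal protein gene Rplp0 (-2.90 ± 0.58) were also lower in EOM.

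Ckm, the muscle creatine kinase, had a difference of 4.64 ± 1.38 at day 0 (adjusted p = 0.0383), with a within-group range of up to 6.6 log2 units among replicate arrays. The range was at least 3 log2 units in at least 1 group for Krt5, Lcn2, Pdk4, Krt1, Hbb and Hbb-b1.

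By list at day 0, 7 of 20 fatty acid genes were lower in EOM (13 lower and 1 higher adjusted over the list alone), including Cd36, a fatty acid transporter (-2.0 ± 0.36), Fabp3, the muscle fatty acid binding protein (-1.86 ± 0.20), and Acsl1 (-1.15 ± 0.23). In the glycolysis and glycogen list, 5 of 16 were lower (also 5 adjusted over the list alone), among them Fbp2, the muscle fructose bisphosphatase (-2.05 ± 0.35), the enolase Eno3 (-1.31 ± 0.20) and the glycogen phosphorylase Pygm (-1.18 ± 0.20). In the slow fibre list, 4 of 12 were lower, with Car3, a carbonic anhydrase of slow fibres, at -2.20 ± 0.35 and the light chain Myl3 at -1.51 ± 0.29. Adjusted over the list alone, 7 were lower and 1 was higher. The oxidative phosphorylation list had 3 of 38 members lower (8 adjusted over the list alone), led by the mitochondrial creatine kinase Ckmt2 (-1.63 ± 0.25). Of the dystrophin complex and sarcolemma list, 4 of 13 were lower (6 adjusted over the list alone), among them Des, the muscle intermediate filament desmin (-0.91 ± 0.27), and Cav3, the muscle caveolin (-0.73 ± 0.20). The developmental isoform list had 2 of 12 members lower (also 2 adjusted over the list alone), the perinatal myosin Myh8 (-1.04 ± 0.28) and Chrng, the fetal subunit of the acetylcholine receptor (-0.70 ± 0.17). The camera test across genes put these 6 lists lower in EOM, with adjusted p from 8.24e-12 for fatty acids to 0.00145 for developmental isoforms. Without the probe sets that reach the top 5% of values, a setting chosen after seeing the data, the slow fibre list (adjusted p = 0.502, with a median of 0.46 over the 4 genes left) and the dystrophin list (adjusted p = 0.14) were not called, and the other 4 were.

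Of the 15 measured adult fast fibre genes, Myh4 (-1.87 ± 0.37), Mybpc2 (-1.66 ± 0.33), Tnni2 (-0.79 ± 0.20) and 1 other were lower in EOM and Ckm was higher, with the same counts adjusted over the list alone. The camera test of that list gave an adjusted p of 0.0419, and adjusted p = 0.382 with an estimated correlation. The ribosomal protein list had 6 of 40 members lower (also 6 adjusted over the list alone), among them Rplp0 and Rps3 (-2.12 ± 0.37), with a camera adjusted p of 1.7e-08 and adjusted p = 0.14 with an estimated correlation. In the insulin-like growth factor list 0 of 13 members passed limma's test over all genes (4 at an unadjusted p under 0.05), 3 were lower and 1 higher adjusted over the list alone, and camera placed it lower (adjusted p = 0.0411, and adjusted p = 0.371 without the top 5% probe sets). Its largest differences were Igfbp5 at 1.93 ± 0.66 and Igf2 at -1.76 ± 0.66, with adjusted p of 0.087 and 0.126. Of the other myosins, Myh13, the myosin specific to extraocular muscle (-0.30 ± 0.60), Myh2 (0.01 ± 0.27) and the embryonic Myh3 (0.16 ± 0.39) did not differ past the threshold, although another probe set of Myh3 was lower in EOM.

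In the lacrimal and Harderian gland list at day 0, 6 of 11 members were higher in EOM (also 6 adjusted over the list alone), including Krt19, Lcn2, a lipocalin secreted by epithelia (3.26 ± 0.57), Krt8 (3.25 ± 0.38) and Krt18 (3.02 ± 0.45), and camera gave an adjusted p of 1.2e-06. Of the Schwann cell and axon markers, 4 of 20 were higher, including Sox10, Mbp, the myelin basic protein (1.67 ± 0.49), and Nefm, a neurofilament subunit (1.59 ± 0.45), while Ngfr, the low-affinity neurotrophin receptor, was lower (-1.31 ± 0.40). Counts adjusted over the list alone were the same and the camera adjusted p was 0.0419, or 0.14 without the top 5% probe sets. Pax6, a transcription factor of eye development, was the 1 of 10 eye markers that passed the test (also 1 adjusted over the list alone), and was at least 9.49-fold higher because all 3 leg arrays were at the floor. Of 28 leukocyte markers 0 passed limma's test at day 0 (2 at an unadjusted p under 0.05), and of 27 proteasome genes also 0 (0 at an unadjusted p under 0.05), with the same counts of 0 adjusted over the list alone. Of 12 erythroid markers, Hbb and Hbb-b1 were lower and the embryonic globin Hbe1 was higher (2.01 ± 0.49), and of 16 adipocyte markers Fabp4 was lower (-1.70 ± 0.25), as were 2 others, and Scd2, a fatty acid desaturase, was higher (1.27 ± 0.29). Cell cycle genes Ccnd2 (1.73 ± 0.26) and Ccnd1 (1.54 ± 0.25) were the 2 of 26 past the test, both higher. Agrn, which clusters acetylcholine receptors, was higher by 1.06 ± 0.19, and Chrnd and Chrng, receptor subunits, were lower, in the neuromuscular junction list of 15. None of these last 4 lists and none of the leukocyte, eye and proteasome lists passed the camera test at day 0.

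**Figure D2:**
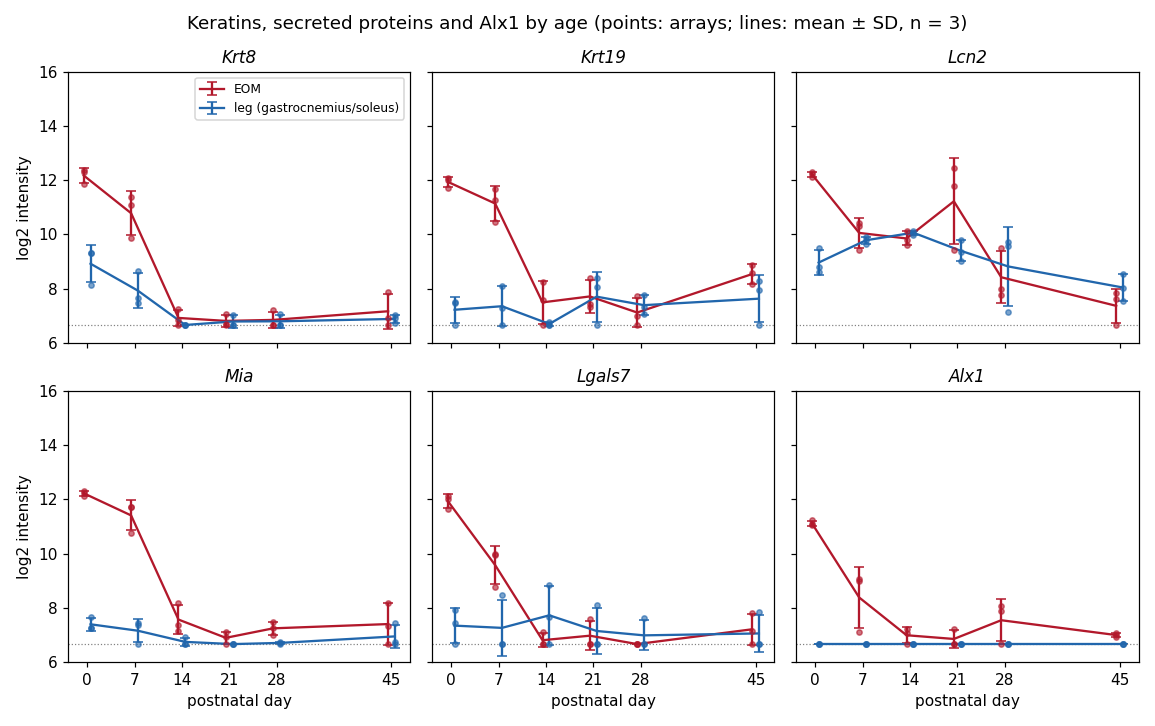
Log2 intensity (vertical axis) against postnatal day (horizontal axis) of 6 genes that were higher in EOM at day 0. Points are arrays, lines are means with SD of 3 arrays, and the dotted line is the detection floor (log2 6.66), at which Alx1 lay on all 3 leg arrays at day 0.

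In all, 422 of 6672 probe sets differed at day 0, with 262 higher and 160 lower in EOM, and 304 of them differed 2-fold or more. With each array scaled to the same median, the split was 205 higher and 229 lower, and the median of all probe sets moved by -0.127 log2 units. Without leg day 0 replicate 1 the count was 278.

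At day 7, Mybpc2, the fast myosin-binding protein C, was lower in EOM by -4.94 ± 0.33 (adjusted p = 1.85e-11), with EOM close to the floor, Myh4, the fast IIB myosin, was lower by -2.84 ± 0.37, and Dhrs7c and Fbp2 were lower by -3.36 ± 0.40 and -2.94 ± 0.35. Myh13 was higher in EOM by 2.40 ± 0.60 (adjusted p = 0.0132), the first age of the series at which it differed. Ctse, an aspartic protease (4.57 ± 0.88), and Mia (4.25 ± 0.34) were higher in EOM, and Sox10 was at least 17.0-fold higher, with leg at the floor. The slow myosin Myh7 was lower in EOM by -0.71 ± 0.21, while Myh8 (-0.70 ± 0.28) and Chrne, the adult receptor subunit (-0.05 ± 0.24), did not pass. Of the probe sets, 332 differed, 222 higher and 110 lower in EOM, 250 of them 2-fold or more. With arrays scaled to the same median the split was 172 higher and 132 lower, and the 6 arrays compared alone gave 221. Without EOM replicate 1 or 2 the count was 204 or 190, and without leg replicate 1 or 2 it was 191 or 216.

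At day 14, Myh13 was 34.4-fold higher in EOM (5.10 ± 0.60, adjusted p = 1.07e-06). Stk39, a kinase that regulates ion cotransport, was higher by 3.21 ± 0.52, and Aldoa, a glycolytic aldolase, by 3.64 ± 1.07, with a within-group range of up to 6.05 log2 units. Lower in EOM were Gpd1, the glycerol-3-phosphate dehydrogenase (-3.88 ± 0.65), Mybpc2 (-3.22 ± 0.33) and Dhrs7c (-2.98 ± 0.40). Chrne was higher in EOM by 0.91 ± 0.24 (adjusted p = 0.0217), while Myh4 (-0.15 ± 0.37), Myh2 (-0.46 ± 0.27) and Myh8 (0.12 ± 0.28) did not pass. All Myh4 and Myh2 arrays read 14.16 or more at this age, near the top of the scale, so a difference could be missed. In this comparison 328 probe sets differed, 174 higher and 154 lower, 230 of them 2-fold or more. The count was 176 from the 6 arrays compared alone, and 215 without the probe sets that reach the top 5% of values, a setting chosen after seeing the data. It was 218 without EOM replicate 2, and 193 or 177 without leg replicate 1 or 2.

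At day 21, Myh13 remained higher in EOM by 5.57 ± 0.60, with Prune2 (3.21 ± 0.48) and Stk39 (2.88 ± 0.52) next. Myh8 was 2.92-fold higher in EOM (1.55 ± 0.28, adjusted p = 0.00112), after being lower there at day 0. Resp18, a protein of secretory granules (-1.92 ± 0.54), and Fbp2 (-1.55 ± 0.35) were lower, and Prss22, a serine protease, was at least 3.21-fold lower, with EOM at the floor. Of the 269 probe sets that differed, 232 were higher and 37 lower, and 186 differed 2-fold or more. Without EOM replicate 3 the count was 82, without leg replicate 1 or 2 it was 122 or 145, with the 6 arrays compared alone 22, and with quantile normalization 179. Without arrays numbered 3, a setting chosen after seeing the data, it was 150. Scaled to the same median the split was 136 higher and 62 lower, with a shift of -0.132 in the median of all probe sets.

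At day 28, the perinatal myosin Myh8 was 21.6-fold higher in EOM (4.43 ± 0.28, adjusted p = 4.98e-12), and the embryonic myosin Myh3 was higher by 2.06 ± 0.39. Myh13 (5.10 ± 0.60), Stk39 (4.63 ± 0.52) and Chrne (1.59 ± 0.24) were higher as well. Gpd1 (-2.97 ± 0.65), Tspan8, a tetraspanin of epithelial membranes (-2.94 ± 0.40), and Ppp1r1a, an inhibitor of protein phosphatase (-2.84 ± 0.30), were lower in EOM. Myh7 (-0.57 ± 0.21) and Myh2 (-0.67 ± 0.27) did not pass. There were 788 probe sets past the test, 509 higher and 279 lower, 495 of them 2-fold or more. With arrays scaled to the same median, 379 were higher and 382 lower, and the median of all probe sets moved by -0.108; the 6 arrays compared alone gave 432, and all but EOM replicate 2 gave 515.

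At day 45, the oldest age, Myh8 was at least 67.7-fold higher in EOM (6.08 ± 0.28, adjusted p = 8.72e-16), at a level of 13.23 in EOM and 7.15 in leg on the log2 scale with 1 of 3 leg arrays at the floor, and Myh13 was higher by 5.89 ± 0.60. Stk39 (4.23 ± 0.52) and Myh3 (3.54 ± 0.39) came next. The mitochondrial adenylate kinase Ak4 (3.48 ± 0.45), the glutathione transferase Mgst1 (3.43 ± 0.61), Ndrg4 (3.30 ± 0.39) and Prune2 (3.15 ± 0.48) followed. Lower in EOM were Gpd1 (-3.34 ± 0.65), Atp1b2, a subunit of the sodium pump (-2.57 ± 0.41), Ppp1r1a (-2.42 ± 0.30), Pdk4 (-2.42 ± 0.61), the scaffold protein Homer2 (-2.41 ± 0.34), Pfkfb1, which sets the level of fructose bisphosphate (-2.29 ± 0.49), Dhrs7c (-2.15 ± 0.40) and Gcn1 (-2.08 ± 0.47). The adult fast myosin Myh1 was lower in EOM by -1.11 ± 0.34, while Myh2 (-0.55 ± 0.27), Myh4 (-0.55 ± 0.37) and Myh7 (0.00 ± 0.21) did not pass, and another probe set of Myh7 was lower in EOM past the test. From day 21 on, all leg arrays of Myh2 and Myh4 read 14.49 or more, near the top of the scale, so differences could be missed.

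By list at day 45, 7 of 16 glycolysis and glycogen genes were lower in EOM (8 adjusted over the list alone), with Gpd1, Pfkfb1, Fbp2 (-1.97 ± 0.35) and Phka1, a phosphorylase kinase subunit (-1.78 ± 0.45). Camera gave an adjusted p of 1.57e-05, and adjusted p = 0.078 with an estimated correlation. Of 12 slow fibre genes, 6 were lower, including Car3 (-2.02 ± 0.35) and Csrp3, a protein of the Z disc (-1.57 ± 0.23), and Pln, an inhibitor of the calcium pump, was higher (1.67 ± 0.36). Counts were 7 lower and 2 higher adjusted over the list alone. Camera placed the slow fibre list lower (adjusted p = 0.00207, and adjusted p = 0.078 with an estimated correlation). Of 34 matrix genes, 10 were higher in EOM (13 adjusted over the list alone), among them Lum, a proteoglycan (1.74 ± 0.27), the elastic fibre protein Fbln5 (1.5 ± 0.21) and Postn (1.28 ± 0.21), with a camera adjusted p of 0.000928 and adjusted p = 0.0909 with an estimated correlation. Of 15 neuromuscular junction genes, 5 were higher (6 adjusted over the list alone), including the receptor subunits Chrna1 (1.39 ± 0.18), Chrne (1.35 ± 0.24) and Chrnd (1.15 ± 0.18). For this list camera gave an adjusted p of 0.00352, and adjusted p = 0.214 with an estimated correlation. Chrng did not differ past the threshold (-0.02 ± 0.17). Of 25 antioxidant genes, 4 were higher (5 adjusted over the list alone), among them the metallothionein Mt3 (1.79 ± 0.43) and Gstm2 (1.51 ± 0.25), with an adjusted p of 0.025, and adjusted p = 0.299 with an estimated correlation.

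Of 20 Schwann cell and axon markers at day 45, 5 were higher in EOM (8 higher and 1 lower adjusted over the list alone), with the myelin genes Cnp (2.28 ± 0.43), Mbp (1.76 ± 0.49), Prx (1.60 ± 0.26) and Pmp22 (1.58 ± 0.25). Their camera adjusted p was 0.0175, and adjusted p = 0.078 with an estimated correlation. Vdac1, an outer membrane channel of mitochondria (-1.01 ± 0.33), was the 1 of 38 oxidative phosphorylation genes past the test (0 adjusted over the list alone), with a camera adjusted p of 0.00477, and adjusted p = 0.462 with an estimated correlation. In the ribosomal list, Rps24 (-1.21 ± 0.34) and Rpl36 (-0.50 ± 0.16) were the 2 of 40 that were lower (0 adjusted over the list alone), with a camera adjusted p of 0.0304, and adjusted p = 0.633 with an estimated correlation. The gland list, higher at day 0, had 0 of 11 members past limma's test at day 45, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05), and camera gave an adjusted p of 0.924. Without a camera call, 5 of 16 adipocyte markers were higher and 1 was lower (the same adjusted over the list alone), with the desaturases Scd (2.97 ± 0.51) and Scd2 (2.50 ± 0.29) and the lipid droplet protein Cidea (1.98 ± 0.28), and 5 of 15 endothelial and smooth muscle markers were higher, with the smooth muscle myosin Myh11 at 1.74 ± 0.41. Igf1, the growth factor, was higher by 1.94 ± 0.35, and Fst, an inhibitor of myostatin, by 2.15 ± 0.37, while Myog, a myogenic regulator, was lower by -1.67 ± 0.31. The comparison called 706 probe sets, 460 higher and 246 lower in EOM, with 457 differing 2-fold or more. The 6 arrays compared alone gave 132, and without leg replicate 2 the count was 439. EOM replicates at day 45 correlated at 0.915, 0.894 and 0.877, the last the lowest of any group. The error pooled over all groups may therefore be too small for this comparison.

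The next comparison asked what changed within EOM between birth and day 45. Mybpc2 rose at least 84.9-fold (6.41 ± 0.33, adjusted p = 4.02e-15), with 1 of 3 arrays at the floor at day 0. Myh13 rose by 6.24 ± 0.60, Myh4 by 5.86 ± 0.37, Rpl3l, a muscle form of a ribosomal protein, by 5.15 ± 0.35, Pvalb, the calcium buffer of fast fibres, by 4.96 ± 0.33, and Myh2 27.8-fold (4.80 ± 0.27). Myoc, the secreted protein myocilin (4.61 ± 0.33), and Rplp0 (4.51 ± 0.58) also rose. Agtr2, an angiotensin receptor of fetal tissues, fell at least 37.7-fold, to the floor on all 3 arrays at day 45. Of the genes higher in EOM at day 0, Krt8 fell by -5.01 ± 0.38, Lcn2 by -4.86 ± 0.57, Mia by -4.83 ± 0.34, Lgals7 by -4.73 ± 0.53, Alx1 by -4.13 ± 0.37 and Krt5 by -4.10 ± 0.85. The fall of Lcn2 was not steady, with EOM arrays at 11.79, 9.43 and 12.45 on the log2 scale at day 21. Col2a1, the collagen of cartilage, fell by 3.97 ± 0.41 on the log2 scale. Myh8 (-0.07 ± 0.28) and Myh3 (0.33 ± 0.39) did not change past the threshold in EOM, although another probe set of Myh3 fell. The Myh3 probe set used here read 13.58 or more on all EOM arrays of both ages, bright enough that a change could be understated.

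The oxidative phosphorylation, fatty acid and glycolysis lists rose in EOM. Of 38 oxidative phosphorylation genes, 29 rose and 0 fell (the same adjusted over the list alone), including Ckmt2 (3.46 ± 0.25), Idh3g (1.89 ± 0.22) and the succinate dehydrogenase subunit Sdha (1.74 ± 0.17). Of 20 fatty acid genes, 17 rose (18 adjusted over the list alone), with Fabp3 at 4.01 ± 0.20, Acadm, a dehydrogenase of medium-chain fatty acids, at 3.46 ± 0.18, and Cd36 at 2.92 ± 0.36. Of 16 glycolysis and glycogen genes, 13 rose (also 13 adjusted over the list alone), including Phka1 (2.73 ± 0.45) and Pgm1 (1.85 ± 0.15). Of 26 cell cycle genes, 21 fell and 0 rose (22 fell adjusted over the list alone), with the topoisomerase Top2a at -3.08 ± 0.26, Cdk1 at -3.06 ± 0.25 and the replication helicase subunit Mcm6 at -3.03 ± 0.24. Camera adjusted p-values were 1.03e-14, 2.17e-14, 1.41e-07 and 9.3e-14 in that order. Of 12 developmental isoforms, 4 fell (also 4 adjusted over the list alone), the embryonic light chain Myl4 (-3.96 ± 0.33), Myog (-2.90 ± 0.31), Tnnt2 (-1.56 ± 0.44) and the intermediate filament Nes (-1.49 ± 0.19), with a camera adjusted p of 0.0145.

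Of 15 adult fast fibre genes in EOM, 6 rose (also 6 adjusted over the list alone). The list's median was -0.02 and its mean 1.11, and camera gave a rise (adjusted p = 0.000532, and adjusted p = 0.144 with an estimated correlation). Of 34 matrix genes, 15 fell and 1 rose (15 and 2 adjusted over the list alone), with the proteoglycan Vcan at -3.85 ± 0.46 and Lox, which cross-links collagen, at -3.72 ± 0.31. For matrix genes the camera adjusted p was 0.0064, and adjusted p = 0.144 with an estimated correlation. Of 24 calcium handling genes, 10 rose and 2 fell (the same adjusted over the list alone), including Asph (2.51 ± 0.20) and the calcium channel Cacna1s (1.96 ± 0.26), while Casq2, the calsequestrin of slow and cardiac muscle, fell (-1.60 ± 0.23). For calcium handling the adjusted p was 0.0121, and adjusted p = 0.112 with an estimated correlation. Of 25 antioxidant genes, 10 rose and 3 fell (13 and 3 adjusted over the list alone), with the peroxidase Gpx3 at 2.48 ± 0.27 and Sod2 at 2.30 ± 0.32. For antioxidant genes the adjusted p was 0.0223, and adjusted p = 0.247 with an estimated correlation. Of 11 gland genes, 5 fell and 2 rose (the same adjusted over the list alone), with a camera adjusted p of 0.0475, and adjusted p = 0.321 with an estimated correlation. Chrne rose by 2.36 ± 0.24, Erbb2 fell by 1.43 ± 0.38 and Agrn by 1.35 ± 0.19, in the neuromuscular list. Camera did not call that list (adjusted p = 0.599). Of 17 immediate early genes, 3 fell, including Egr1 (-2.03 ± 0.35) and Myc (-1.96 ± 0.33), and 2 rose, Hspa1a (1.74 ± 0.27) and Gadd45a (1.53 ± 0.20), without a camera call. In EOM the probe set of Igf2 used here rose (4.07 ± 0.66) and another fell past the test. The count was 2090 probe sets, 861 higher and 1229 lower at day 45, with 1421 differing 2-fold or more. With arrays scaled to the same median it was 1070 higher and 1004 lower, and the median of all probe sets moved by 0.134. With day 14 in place of day 0, chosen after seeing the data, 322 probe sets differed.

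**Figure D3:**
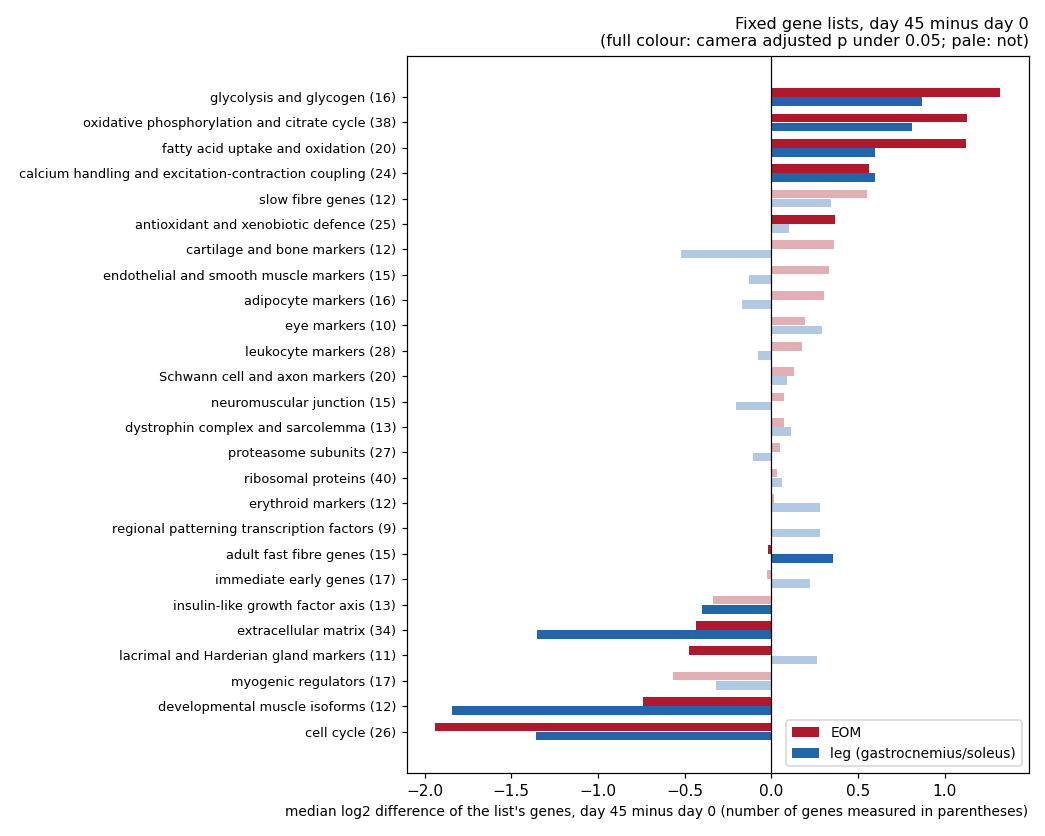
Median log2 difference between day 45 and day 0 (horizontal axis) of the genes of each fixed list (vertical axis) in EOM and leg, in full colour where camera gave an adjusted p under 0.05. The cell cycle list was lower in both muscles (medians -1.94 and -1.36), and the oxidative phosphorylation list higher in both (1.13 and 0.81). With an estimated correlation, camera gave the oxidative phosphorylation list in leg an adjusted p of 0.0551.

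In leg, the perinatal myosin Myh8 fell at least 146-fold between day 0 and day 45 (-7.19 ± 0.28, adjusted p = 3.85e-18), with 1 of 3 arrays at the floor at day 45, and Myh3 fell by 3.05 ± 0.39 on the log2 scale, although another probe set of Myh3 rose past the test. Pvalb rose by 5.58 ± 0.33, Mybpc2 by 5.55 ± 0.33, Myh2 by 5.36 ± 0.27 and Myh4 by 4.54 ± 0.37, all 4 with arrays near the top of the scale at day 45. Rpl3l (5.04 ± 0.35), Gpd1 (4.56 ± 0.65) and Phka1 (4.01 ± 0.45) rose too, and Myoc rose at least 22.8-fold from the floor at day 0. Agtr2 fell at least 43.2-fold, to the floor at day 45. Gpc3, a glypican (-5.21 ± 0.22), Col2a1 (-5.07 ± 0.41), the imprinted gene Ndn (-4.72 ± 0.35), Gatm, an enzyme of creatine synthesis (-4.54 ± 0.35), Myl4 (-4.50 ± 0.33) and Nrk (-4.30 ± 0.40) fell. Myh13 did not change past the threshold (0.06 ± 0.60).

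By list in leg, 10 of 12 developmental isoforms fell and 1 rose (the same adjusted over the list alone), with Tnnt2 at -4.06 ± 0.44 and the cardiac actin Actc1 at 4.76 ± 1.85, with a within-group range of up to 8.7 log2 units for Actc1. Camera placed the list lower (adjusted p = 1.38e-07). Of 26 cell cycle genes, 21 fell and 0 rose (22 fell and 1 rose adjusted over the list alone), with Mcm6 at -3.12 ± 0.24 and Stmn1, a regulator of microtubules, at -2.81 ± 0.23. Of 34 matrix genes, 19 fell and 1 rose (the same adjusted over the list alone), with Vcan at -4.20 ± 0.46, Postn at -3.39 ± 0.21 and Lox at -3.15 ± 0.31. Of 38 oxidative phosphorylation genes, 26 rose and 1 fell (28 and 1 adjusted over the list alone), including Ckmt2 (2.10 ± 0.25) and Cox6c (1.60 ± 0.24). Here camera gave an adjusted p of 9.1e-10, and adjusted p = 0.0551 with an estimated correlation. Of 20 fatty acid genes, 10 rose (also 10 adjusted over the list alone), including Acadm (2.45 ± 0.18) and Fabp3 (2.26 ± 0.20). Among 16 glycolysis and glycogen genes, 12 rose and 1 fell (the same adjusted over the list alone), including Pfkfb1 (3.74 ± 0.49). The camera adjusted p-values of the cell cycle, matrix, fatty acid and glycolysis lists were 2.74e-11, 4.08e-09, 3.26e-05 and 2.23e-06.

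Of 15 adult fast fibre genes in leg, 7 rose and 0 fell (the same adjusted over the list alone), with a camera adjusted p of 0.000877, and adjusted p = 0.16 with an estimated correlation. Of 24 calcium handling genes, 9 rose and 1 fell (10 and 2 adjusted over the list alone), with Asph at 3.12 ± 0.20, the chloride channel Clcn1 at 2.39 ± 0.53 and Casq2 at -2.82 ± 0.23. Their adjusted p was 0.00545, and adjusted p = 0.0588 with an estimated correlation. Of 13 genes of the insulin-like growth factor list, 5 fell and 1 rose (the same adjusted over the list alone), with Igfbp3 at -2.99 ± 0.30, Igf2r at -2.99 ± 0.24 and Igf1 at -2.35 ± 0.35. Camera's adjusted p was 0.032, and adjusted p = 0.0551 with an estimated correlation. The probe set of Igf2 used here rose (2.91 ± 0.66) and another fell. Of 15 neuromuscular junction genes, 6 fell and 2 rose (the same adjusted over the list alone), with Chrnd at -2.15 ± 0.18, Chrna1 at -1.38 ± 0.18, Chrng at -0.98 ± 0.17 and Chrne at 1.18 ± 0.24, without a camera call. Of 9 regional patterning factors, Meox2 (-1.91 ± 0.31) and Pitx3 (-0.56 ± 0.22) fell and Msx2 (1.16 ± 0.30) and Dlx5 (1.16 ± 0.39) rose, without a camera call. Of 17 myogenic regulators, 7 fell and 1 rose, and of 12 cartilage and bone markers 3 fell and 3 rose, again without a call. Replicate arrays of a group ranged over up to 4.09 log2 units for Gpd1 and 3.47 for Myh13. In leg, 2190 probe sets differed, 959 higher and 1231 lower at day 45, and 1537 of them 2-fold or more; 899 differed with day 14 in place of day 0.

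The changes of the 2 muscles were set side by side: 543 probe sets rose in both (124 expected from independent lists) and 797 fell in both (227 expected), while 7 rose in EOM and fell in leg and 9 did the opposite. Across probe sets, which are not independent replicates, the log2 changes correlated at 0.722. Over all ages, 2092 probe sets changed in EOM and 2396 in leg by the moderated F test; without day 0, a setting chosen after seeing the data, the counts were 1245 and 1785. The interval with the largest step was most often day 7 to day 14, for 43.9% of these probe sets in EOM and 32.2% in leg.

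**Figure D4:**
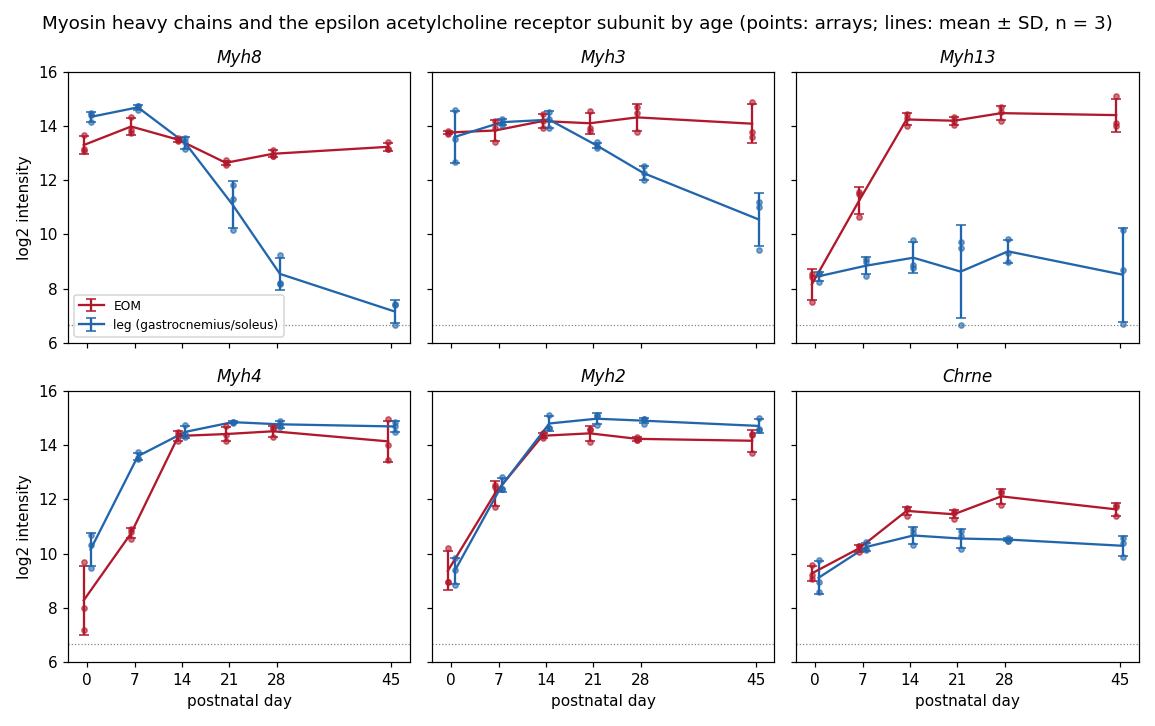
Log2 intensity (vertical axis) against postnatal day (horizontal axis) of 5 myosin heavy chains and the adult acetylcholine receptor subunit Chrne in EOM and leg. Points are arrays and lines are means with SD of 3 arrays; at day 45 Myh8 was at 13.23 in EOM and 7.15 in leg, and Myh13 at 14.40 and 8.51.

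Whether the change from day 0 to day 45 differed between the muscles was tested directly, as EOM change minus leg change. Myh8, which fell in leg and did not change past the threshold in EOM, differed by 7.12 ± 0.40 (adjusted p = 1.63e-13), Myh13 by 6.18 ± 0.84 and Myh3 by 3.38 ± 0.55. Klk1, a tissue kallikrein (4.22 ± 0.41), Ak4 (3.36 ± 0.63), Krt1 (3.21 ± 0.79), Ndrg4 (3.03 ± 0.55) and Stk39 (3.00 ± 0.73) were the other genes with the largest positive differences. Probe sets of Stk39 passed in opposite directions in leg between day 0 and day 45, though not for the difference itself. The largest negative differences included Tspan8 (-4.73 ± 0.56), Lgals7 (-4.45 ± 0.75), Mia (-4.38 ± 0.49), Lcn2 (-3.94 ± 0.81), Krt19 (-3.81 ± 0.68), the copper carrier Cp (-3.61 ± 0.66) and the epithelial adhesion molecule Epcam (-3.33 ± 0.70). Differences of Myh1 (-1.37 ± 0.48), Myh2 (-0.56 ± 0.39), Myh4 (1.32 ± 0.53), Myh7 (0.35 ± 0.30) and Chrng (0.67 ± 0.24) did not pass.

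By list, the change was more positive in EOM for 4 of 12 developmental isoforms (5 higher and 1 lower adjusted over the list alone), including Tnnt2 (2.50 ± 0.63) and Vim (1.06 ± 0.28), with a camera adjusted p of 2.2e-05, or 0.183 without the top 5% probe sets. It was more positive for 6 of 20 fatty acid genes (8 adjusted over the list alone), including Cd36 (2.26 ± 0.51), Fabp3 (1.74 ± 0.28) and Acsl1 (1.24 ± 0.32), with an adjusted p of 1.82e-09. It was more positive for 6 of 34 matrix genes (10 adjusted over the list alone), including Thbs4 (2.33 ± 0.38), Fmod (1.91 ± 0.46) and Postn (1.45 ± 0.30), with an adjusted p of 1.21e-06. In the neuromuscular junction list, Chrnd (2.09 ± 0.26), Chrna1 (1.57 ± 0.25) and Chrne (1.19 ± 0.34) were the 3 of 15 past the test (5 adjusted over the list alone), with an adjusted p of 0.000555, and adjusted p = 0.101 with an estimated correlation. Igf1 (2.60 ± 0.50) and Igf2r (1.20 ± 0.34) were 2 of 13 in the insulin-like growth factor list (also 2 adjusted over the list alone; camera adjusted p = 0.0145, and adjusted p = 0.299 without the top 5% probe sets). In the adipocyte list, Cidea (2.68 ± 0.40), Fabp4 (1.64 ± 0.36) and Acly (1.58 ± 0.37) were 3 of 16 (9 higher and 1 lower adjusted over the list alone), with an adjusted p of 0.000117, and adjusted p = 0.0503 with an estimated correlation. The gland list had 4 of 11 members lower (6 adjusted over the list alone), Lcn2, Krt19, Krt8 (-2.97 ± 0.54) and Krt18 (-2.28 ± 0.63), with an adjusted p of 6.53e-05.

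Camera also called the dystrophin and sarcolemma list, with Vim and Itga7 (1.03 ± 0.25) as 2 of 13 past the test (3 adjusted over the list alone; adjusted p = 0.0319, and adjusted p = 0.0744 with an estimated correlation). It called the oxidative phosphorylation list, with Ckmt2 (1.36 ± 0.35) as 1 of 38 (also 1 adjusted over the list alone; adjusted p = 0.0145, and adjusted p = 0.568 with an estimated correlation). It called the ribosomal list, with Rps3 (1.83 ± 0.52) and Rpl3 (1.56 ± 0.42) as 2 of 40 (3 adjusted over the list alone; adjusted p = 0.0319, and adjusted p = 0.651 with an estimated correlation). For both Rps3 and Rpl3, probe sets passed in opposite directions in EOM between day 0 and day 45, though not for the difference itself. Among lists without a call, the immediate early genes Jun (-2.20 ± 0.36), Cebpb (-2.06 ± 0.51) and Nr4a1 (-1.94 ± 0.43) were lower and Gadd45a (1.79 ± 0.29) higher. In all, 247 probe sets differed in their change, 150 more positive and 97 more negative in EOM, 235 of them 2-fold or more. The 12 arrays compared alone gave 116, leaving out the probe sets that reach the top 5% of values gave 150, and day 14 in place of day 0 gave 10, the last 2 settings chosen after seeing the data.

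Over the 5 comparisons in which lists were tested, 48 of 130 list tests passed the threshold and 24 of the 48 also passed with an estimated correlation; those that did not are given with their values beside each list. The median, mean and test differed in sign in 21 of 130, and only the adult fast fibre list in EOM had passed the threshold among these. Without the top 5% probe sets, 23 of the 48 stayed called. With quantile normalization 9 of the 48 calls were lost, among them the developmental isoforms (adjusted p = 0.0623) and Schwann cell markers (adjusted p = 0.0613) at day 0 and the oxidative phosphorylation list (adjusted p = 0.395) at day 45. With arrays scaled to the same median 3 were lost, and neither scaling turned the direction of a called list.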

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

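Among the tests below, those of bright and of dim probe sets, of a lower muscle share, of gland genes without keratins and of a shared batch by number, and the counts of bright cases by group and by array number, were chosen only after the result was seen.

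The change from day 0 to day 45 differed between EOM and leg, by limma's test of the difference itself, for 247 probe sets. Towards EOM were Myh8 7.12, Myh13 6.18, Myh3 3.38, Chrnd 2.09, Chrna1 1.57 and Chrne 1.19 on the log2 scale. So were Ak4 3.36, Cidea 2.68, Cd36 2.26, Fabp3 1.74, Fabp4 1.64, Acly 1.58, Ckmt2 1.36 and Acsl1 1.24. Further ones were Igf1 2.60, Tnnt2 2.50, Thbs4 2.33, Fmod 1.91, Postn 1.45, Igf2r 1.20, Vim 1.06 and Itga7 1.03. Others were Klk1 4.22, Krt1 3.21, Ndrg4 3.03, Stk39 3.00, Rps3 1.83, Gadd45a 1.79 and Rpl3 1.56. Towards leg were Tspan8 -4.73, Lgals7 -4.45, Mia -4.38, Lcn2 -3.94, Krt19 -3.81, Epcam -3.33, Krt8 -2.97 and Krt18 -2.28, with Cp -3.61, Jun -2.20, Cebpb -2.06 and Nr4a1 -1.94.

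By list median, the difference of the changes was 0.747 for adipocyte markers, 0.647 for developmental isoforms, 0.614 for fatty acid genes, 0.55 for the neuromuscular junction, 0.494 for extracellular matrix, 0.413 for the dystrophin complex, 0.354 for insulin-like growth factors, 0.204 for ribosomal proteins, 0.193 for oxidative phosphorylation and -1.37 for gland markers. With an estimated correlation, camera did not call adipocyte markers (adjusted p = 0.0503), the neuromuscular junction (0.101) or the dystrophin complex (0.0744). Nor did it call ribosomal proteins (0.651) or oxidative phosphorylation (0.568). Without arrays numbered 3, camera's direction for oxidative phosphorylation reversed, without a call.

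Most of the epithelial genes named above were higher in EOM at day 0, but the epidermal keratin Krt1 was lower. A lower share of muscle stays open. The gland list lay 1.14 log2 units above the leukocyte list (95% bootstrap interval 0.139 to 3.4). But the gland list holds keratins that are part of the pattern itself, so this test cannot decide. The leukocyte list and the endothelial and smooth muscle list had medians of -0.0849 and -0.0893. Epithelial tissue in the day 0 EOM samples is a candidate explanation: 12 epithelial genes not looked at before had a median difference of 1.08 (0.555 to 2.06), and 6 were higher, including Cldn3 (3.23), Itgb4 (3.14) and Krt14 (2.15). Of these 12, 5 fell in EOM by day 45, among them Cldn3 and Krt14. Itgb4 (-0.0413) and Slc12a2 (0.00946), also higher at day 0, did not change past the test. Ocln fell (-2.08) but had not passed at day 0 (0.641). Secretory gland tissue stays open, with a median of 0.58 (0.0502 to 1.37) over the 8 gland genes other than keratins, an interval that decides neither way, and a difference between the muscles themselves was not tested.

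Very bright probe sets scattered among replicates, and ranges over 3 log2 units occurred in 412 cases of a probe set and group, at all levels of brightness. RNA degradation stays open, because its test is void: the 5 prime Gapdh control lay 1 log2 unit or more above the 3 prime one on 13 of 36 arrays, but the 3 prime control itself ranged over up to 5.31 log2 units within a group. Saturation of the brightest probe sets is a candidate explanation: such ranges made up 4.52% of cases whose highest array was in the brightest range of the scale and 0.671% of those whose highest array lay between log2 11 and 14, a ratio of 6.74, but 39 of the 53 such bright cases were in EOM at day 45, and without that group the ratio was 2.15. Of 87 values more than 3 log2 units below their group median, among probe sets that reach the top 5%, 65 lay on arrays numbered 2, 16 on arrays numbered 1 and 6 on arrays numbered 3, so a property of particular arrays stays open. Noise of dim probe sets stays open for dim cases alone, by a void test: 43.4% of the 412 cases had their highest array below log2 11, where 69.2% of all cases lie and where the floor limits the range, and no biological explanation was tested.

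Arrays numbered 3 deviated together from their group means, along a first component that held 14.6% of the variance within groups. The scatter of the brightest probe sets is argued against as the source, since without them 12 of 12 such arrays still lay on one side of the first component of the deviations. A batch shared by arrays of one number stays open. The summed correlation of same-numbered arrays had a permutation p of 1e-05, the smallest that 100000 permutations can give. That test was chosen after the shared deviation was seen and measures much the same thing. It cannot tell a batch from another cause shared by number. No biological explanation was tested, and the labels name no batch.

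Regrouping the arrays gave fewer calls than the real groups in most comparisons. With only 10 splits of 6 arrays, too few for a share under 0.05, 1 split (the real one) reached the real count in each comparison of 2 groups. The real count and the highest other were 422 and 18 at day 0, 332 and 2 at day 7, 328 and 2 at day 14, 269 and 37 at day 21, 788 and 2 at day 28, 706 and 100 at day 45, 2090 and 3 in EOM over age, and 2190 and 6 in leg over age. Among the 4 splits that part all same-numbered pairs, the highest other was 0, 1 and 1 at days 7, 14 and 21. It was 2, 2 and 37 among those that keep such a pair together. For the F tests 1 of 100 splits, the real one, reached the real count (2092 against 1005 in EOM, 2396 against 1179 in leg). A random order of the arrays is thus unlikely to give these counts. This holds only if replicates were separate animals, which the labels do not say. For the difference of the changes 5 of 100 splits gave 247 or more, so chance was not excluded. The 4 other splits (882, 421, 270 and 257) all kept the muscles intact at day 45, so they carry the difference between the muscles at that age. The split with 882 also kept them intact at day 0, with the muscle labels swapped there, so it adds the differences of both ages. Splits that mixed the muscles at both ages gave at most 41.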

How the results depend on the processing

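The settings that leave out bright probe sets, arrays numbered 3 or day 0, or put day 14 in place of day 0, were chosen after seeing the data. Of 253 named gene values past the test, 163 could be tested under every setting chosen before the data were examined, and 130 of these stayed past it. Of the other 90, whose probe sets some settings leave out, 61 stayed past it where tested, and no value was reversed by such a setting that tested it. With only the arrays compared in the fit, 56 of 277 named gene values lost a call and 1 gained one. Counts are given in the order days 0, 7, 14, 21, 28 and 45, EOM over age, leg over age, F test in EOM, F test in leg, and the difference of the changes. With 1 probe set per gene (3889 tested) they were 253, 212, 195, 176, 479, 407, 1255, 1293, 1257, 1425 and 140, and without suffixed probe sets (4483 tested) 260, 204, 190, 155, 497, 412, 1369, 1406, 1383, 1554 and 140, with fewer probe sets tested. From the arrays compared alone, with fewer arrays, they were 221 at day 7, 176 at day 14, 22 at day 21, 432 at day 28, 132 at day 45 and 116 for the difference. At day 0 the same kind of fit gave 306, so fewer arrays alone may not account for the low counts at days 21 and 45. Quantile normalization gave 179 at day 21. Without the probe sets that reach the top 5% they were 215 at day 14 and 150 for the difference, and without arrays numbered 3, 150 at day 21. With day 14 in place of day 0 they were 322 in EOM, 899 in leg and 10 for the difference, and without day 0 the F test gave 1245 in EOM. Other counts stayed within 1.5 times, and the causes were not tested where none is named.

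Leaving out 1 array gave 278 to 390 at day 0 (lowest without leg replicate 1), 190 to 294 at day 7 (204 and 190 without EOM replicates 1 and 2, 191 and 216 without leg replicates 1 and 2), 177 to 333 at day 14 (218 without EOM replicate 2, 193 and 177 without leg replicates 1 and 2), and 82 to 343 at day 21 (82 without EOM replicate 3, 122 and 145 without leg replicates 1 and 2). It gave 515 to 694 at day 28 (515 without EOM replicate 2), 439 to 764 at day 45 (439 without leg replicate 2), 1693 to 1863 in EOM, 1767 to 2121 in leg, 1775 to 2259 and 2086 to 2404 for the F tests, and 179 to 276 for the difference.

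With the replicate block the counts were 498, 366, 461, 352, 900, 836, 2268, 2399, 2380, 2727 and 337. Correlations of same-numbered arrays did not all exceed 0.1 at days 0 (0.048, 0.1 and 0.054), 28 (0.1, -0.01 and 0.26) and 45 (-0.095, 0.078 and 0.095). Nor did they over age in EOM (-0.099, 0.011 and 0.19) or leg (0.083, 0.041 and -0.042). Missing that cut does not show that the samples were unpaired. Of 277 named gene values, 5 lost and 3 gained a call under the block, and of 130 list tests 2 lost and 2 gained one.

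Of 48 list calls, 24 held with an estimated correlation, and 23 held without the top 5% probe sets, where 27 lists were called in all. Without those probe sets camera's direction reversed for slow fibre genes at day 0 (median 0.46, 4 genes left). It also reversed for adult fast genes in EOM (median -1.29, 3 genes) and leg (median -0.33, 3 genes). The EOM median of the adult fast list was already -0.02 with all probe sets. Camera's direction further reversed for ribosomal proteins in EOM (median -1.26, 7 genes) and in the difference (median -0.21). Without arrays numbered 3, 39 of the 48 calls held and 6 were gained. Gained at day 45 were adult fast fibre genes (adjusted p = 0.00161), calcium handling (0.0163) and adipocyte markers (0.0114). The others gained were adipocyte markers in EOM (0.0288) and immediate early genes at day 0 (0.0359) and in the difference (0.0249). Lost were insulin-like growth factors at day 0 (adjusted p = 0.104), in leg (0.118) and in the difference (0.0811), Schwann cell markers at days 0 (0.0675) and 45 (0.189), antioxidant genes at day 45 (0.0661), gland markers in EOM (0.211), and in the difference the dystrophin complex (0.538) and oxidative phosphorylation (0.914), where camera's direction reversed (median 0.0136). The signal over background limits dim probe sets; up to 23.44% of all values of an array lay at the floor.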

Other observations

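The genes in this part were chosen after their values were seen, and no explanation of them was tested.

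Some genes differed in the same direction between the muscles at all 6 ages, 29 probe sets higher and 9 lower in EOM by limma's test, out of 1579 that differed at 1 or more ages. Myelin genes were among those higher: Mbp by 1.67 to 3.51 log2 units, Mal by 1.12 to 2.36 and Prx, a periaxin of Schwann cells, by 0.881 to 1.95. Apoe, a lipid carrier, was higher by 1.5 to 4.15, the aminopeptidase Anpep by 1.57 to 3.78, the sodium channel Scn7a by 2 to 2.64 and the sodium pump subunit Atp1b1 by 1.35 to 3.06. Cyp1b1 was higher by 1.93 to 4.45. Among those lower were Fbp2 (-1.55 to -2.94), Ampd1, the muscle AMP deaminase (-1.39 to -2.63), Car3 (-1.3 to -2.39) and the calcium channel subunit Cacng1 (-1.18 to -2.62).

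Other genes passed the test in opposite directions at different ages, 35 probe sets in all. Klk1 was lower in EOM at day 0 (-2.28 ± 0.29) and higher at day 45 (1.93 ± 0.29), and so was the receptor subunit Chrnd (-0.94 ± 0.18 and 1.15 ± 0.18). Rbp4, the retinol carrier, changed sides in the same way (-1.71 ± 0.38 and 1.28 ± 0.38). Tspan8 was higher in EOM at day 0 (2.71 ± 0.40) and lower at day 45 (-2.02 ± 0.40), as was Jun (1.04 ± 0.25 and -1.17 ± 0.25). Cd36 was lower at day 0 (-2.0 ± 0.36) and higher at day 28 (1.22 ± 0.36), and did not pass at day 45 (0.26 ± 0.36).

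The differences between the muscles at day 0 and day 45 shared 86 probe sets higher in EOM (18.1 expected from independent lists) and 35 lower (5.9 expected). Those at days 28 and 45 shared 240 higher (35.1 expected) and 125 lower (10.3 expected).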
